A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

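Small RNA was sequenced from seminal plasma extracellular vesicles of 3 Fertile and 3 Sub-fertile rabbit bucks. Per the labels' protocols, vesicles were isolated from 2.5 mL of seminal plasma per replicate by ultracentrifugation and size exclusion chromatography, RNA was extracted with Trizol and a column kit, and libraries were made with a QIAseq miRNA kit. Per the submitters' processing notes, bcl2fastq, Bowtie2 2.2.2, DESeq2 and the genome build OryCun2.0 were used, with no role or order given. Groups and replicate numbers were taken from the labels, which describe 3 biological replicates per group. The design places males by semen quality; no record of fertility was used here.

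The deposited table holds 1 normalized signal per miRNA and library, named CPM by the authors. Column totals ran from 807952 to 1108265, so the values are not plain CPM. Every value was a whole multiple of the smallest value above 0 in its library (largest distance from a whole number 1.46e-11), so whole counts were recovered for every value. The implied scaling factors, 0.971, 0.958, 0.951, 1.24, 1.01 and 0.902 for Fertile replicates 1 to 3 and Sub-fertile replicates 1 to 3, equal the TMM factors that edgeR gives on all 577 rows. The deposited signal thus reads as TMM-scaled CPM, a step inferred from the values. Whether reads or unique molecular identifiers were counted is not given in the sources used here. If reads were counted, PCR copies are not independent molecules. Intervals on counts cover counting error only, while the limma intervals and those of the miR-30 tests rest on the spread between libraries. Recovered counts per library ran from 129387 to 772619, so low miRNAs are measured least precisely in Sub-fertile replicates 1 and 2.

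The deposited values were used with no further scaling. The main test was limma 3.58.1 (R 4.3.3) with an empirical Bayes mean-variance trend on log2(value + 1), two-sided, on the 234 miRNAs with a value of at least 10 in at least 3 of 6 libraries. Fold changes are Sub-fertile over Fertile, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Lists of miRNAs with at least 3 tested members were tested with limma camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Composition measures were compared by an exact permutation test. Pairs of libraries of 1 group were compared by chi-square on their counts, and the lowest chi-square per degree of freedom was 20.3, so no library was a copy of another. The test, its filter, the lists and the naming rule were fixed before the data were examined.

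Named miRNAs are the 10 highest by mean, every miRNA past the threshold, the next 6 by p in each direction, and up to 4 members with the smallest p of each list. Strands of miR-30 hairpins, the other leukocyte miRNAs, miR-133, miR-144, miR-302 and miR-124 outside this rule were chosen after their values were seen. Genomic neighbours were taken from the order of miRNA genes in the RefSeq table of the mOryCun1.1 assembly, which is not the build of the study and served for names and neighbourhood alone. Of the tested miRNAs, 233 of 234 matched a hairpin there, and genes within 10 kb of the next formed a cluster.

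Alternatives were other pseudocounts (0.1, 0.5, 5 and 10), other filters, median-of-ratios scaling, quantile normalization, leaving out the 5 most abundant miRNAs, other limma settings, a replicate block, leaving out each library, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered counts. Plain CPM and thinning of all libraries to 129387 counts were added after the data were examined. The edgeR test on recovered counts called 8 miRNAs. The scripts were tested on 20 simulated sets of libraries at these depths, with 40 miRNAs changed in each. Both groups were drawn from the Fertile mean levels, with the same spread for each miRNA in both groups. No set was thus built with a library apart, such as Sub-fertile replicate 1, and the shares need not hold for these data. Of the 2-fold changes 23.8% were recovered and of the 4-fold changes 70.5%, and 3.58% of calls were false. For arm ratios, 13.3% of 4-fold changes were recovered (6 changed hairpins in each of 20 sets). There were 3 false calls in all, a larger share of the calls than for single miRNAs.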

Results

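MicroRNAs (miRNAs), short RNAs that repress target transcripts, were profiled by small RNA sequencing in extracellular vesicles, the membrane-bound particles that cells release, purified from rabbit seminal plasma. From 14 bucks of a California and New Zealand White cross, aged 10 to 12 months and sampled 8 times over 1 month, 3 males with high and 3 with low semen quality were taken forward. The groups were labelled Fertile and Sub-fertile, so the comparison asks which vesicle miRNAs differ between males parted by semen quality. Each library represents 1 biological replicate prepared from 2.5 mL of seminal plasma, with n = 3 per group.

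The table listed 577 mature miRNAs, of which 368 were above 0 in at least 1 library and 209 were at 0 in all 6 libraries. Recovered whole counts per library were 772619, 536026 and 453675 in Fertile replicates 1, 2 and 3, and 129387, 242078 and 636929 in Sub-fertile replicates 1, 2 and 3. A single count was therefore worth between 1.33 units in Fertile replicate 1 and 6.24 units in Sub-fertile replicate 1 on the deposited scale of scaled CPM, in which counts are divided by library depth. Over the 234 miRNAs tested, log2 profiles of Fertile pairs correlated across miRNAs at r = 0.975 to 0.981, and those of Sub-fertile pairs at 0.916 to 0.959. These r values are across miRNAs, which are not independent replicates. Sub-fertile replicate 1, the shallowest library, stood apart on the first principal component, which carried 40.5% of the variance. The second component, with 28.4%, placed the other 2 Sub-fertile libraries apart from the Fertile ones.

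**Figure D1:**
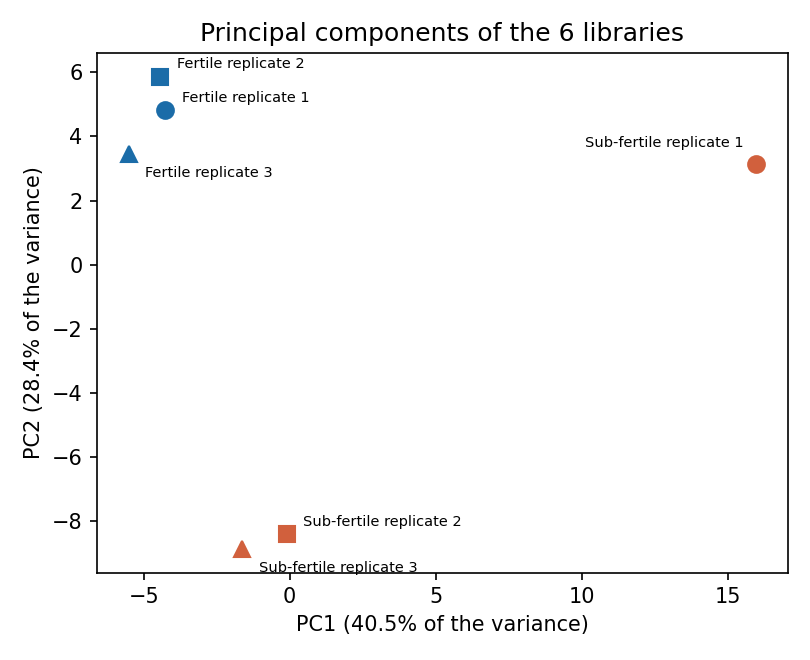
Principal components of log2 miRNA levels in the 6 libraries, with PC1 (40.5% of the variance) on the x axis and PC2 (28.4%) on the y axis, 1 point per library, Fertile in blue and Sub-fertile in orange, and marker shape giving the replicate. Sub-fertile replicate 1 lies at 15.98 on PC1, and the other 5 libraries lie between -5.52 and -0.11.

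The vesicle cargo was dominated by a few miRNAs. The most abundant was let-7b-5p, a member of the let-7 family of developmental timing regulators, with 12.8% ± 1.10 of the total (SD, n = 6). It was followed by let-7a-5p, let-7f-5p, miR-30d-5p, miR-10b-5p, miR-10a-5p, miR-200c-3p, miR-141-3p, miR-1911-5p and miR-29a-3p. These 10 miRNAs held 57.8% ± 2.45 of the total (SD, n = 6). The epithelial miRNAs miR-200c-3p and miR-141-3p together reached 86876 ± 4303 in Fertile and 93983 ± 24890 in Sub-fertile vesicles (SD, n = 3 each). Among miRNAs linked to the testis, miR-508-3p, from an X-chromosome cluster, stood at 9068 ± 1263 in Fertile and 9652 ± 3281 in Sub-fertile (SD, n = 3 each). The muscle miRNAs miR-133a-3p and miR-133b-3p, the erythroid miR-144-3p, the pluripotency miR-302a-3p and the neural miR-124-3p each had 0 counts in every library. A count of 0 allows up to 3 counts, or up to 18.7 units in the shallowest library, and covers counting error only.

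**Figure D2:**
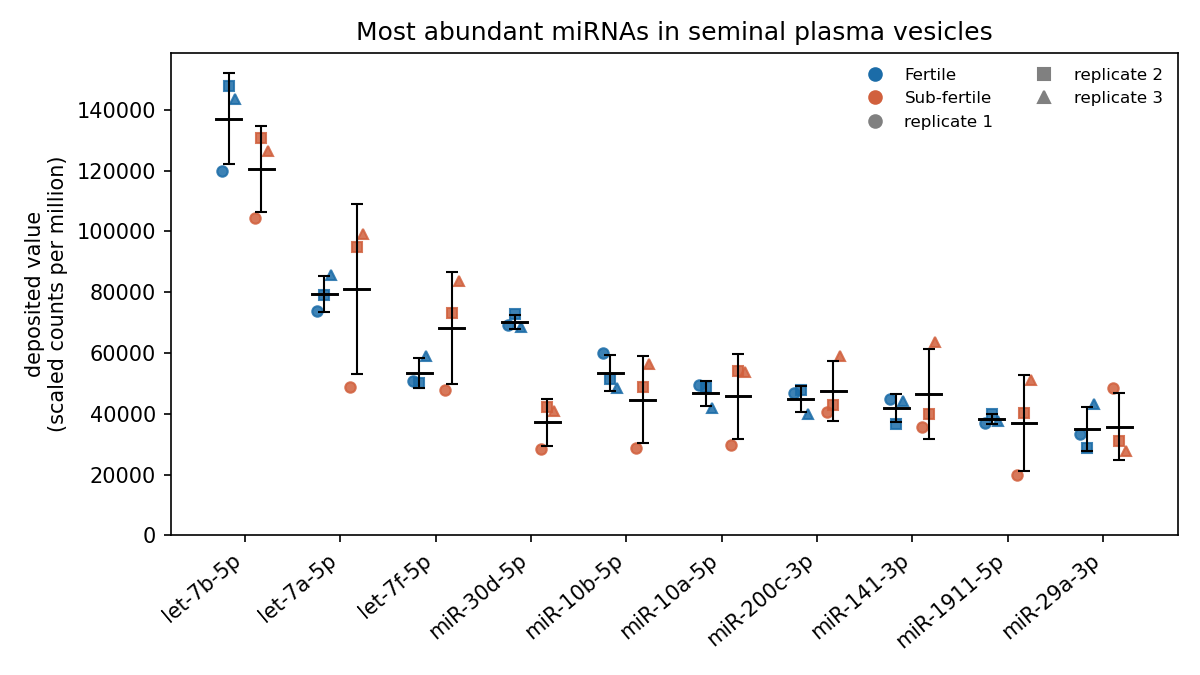
Levels of the 10 most abundant miRNAs as deposited values (scaled CPM, linear axis from 0) in Fertile (blue) and Sub-fertile (orange) libraries, 1 point per library, with horizontal bars for the mean and error bars for the SD (n = 3). Of these 10, miR-30d-5p shows groups that do not overlap, at 70131 ± 2351 in Fertile and 37198 ± 7637 in Sub-fertile.

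Between the groups, 8 of 234 tested miRNAs passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2 higher and 6 lower in Sub-fertile vesicles. The largest change was in miR-206-3p, a miRNA enriched in skeletal muscle, which rose 14.8-fold from 15.3 ± 10.4 to 214.5 ± 38.8 (SD, n = 3 each; limma adjusted p = 0.0062). This fold rested on 7, 14 and 4 counts in the Fertile libraries and 28, 53 and 145 in the Sub-fertile ones, so its size is imprecise. The other increase was in miR-146a-5p, which is induced by inflammatory signalling, from 92.3 ± 30.7 to 400.4 ± 54.6, or 4.45-fold (adjusted p = 0.011). Of the 6 decreases, 3 were in 5p strands of the miR-30 family, of which 5 were measured. The most significant of these, miR-30a-5p, fell 2.42-fold from 41468 ± 2115 to 17245 ± 2460 (adjusted p = 0.0062).

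The decreases of miR-30d-5p (1.91-fold) and miR-30e-5p (2.34-fold) had an adjusted p of 0.035 each. Levels of miR-30e-5p went from 13264 ± 1151 to 5878 ± 1920. The remaining decreases were in miR-676-3p, from 795.3 ± 149.9 to 278.5 ± 57.7 (2.86-fold, adjusted p = 0.018), and in miR-27b-3p, from 4305 ± 1417 to 1568 ± 359 (2.70-fold, adjusted p = 0.030). The sixth, miR-190b-5p, fell 4.06-fold from 205.9 ± 69.9 to 50.0 ± 18.0 (adjusted p = 0.035), on 8 to 28 counts per Sub-fertile library. For each of the 8, all 3 Sub-fertile libraries lay on the same side of all 3 Fertile libraries. Non-overlapping groups were found for 22 miRNAs above and 38 below, 25.6% of those tested, where chance gives 10%. At an unadjusted p under 0.05 there were 45 miRNAs, 15 higher and 30 lower, against 11.7 expected by chance.

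**Figure D3:**
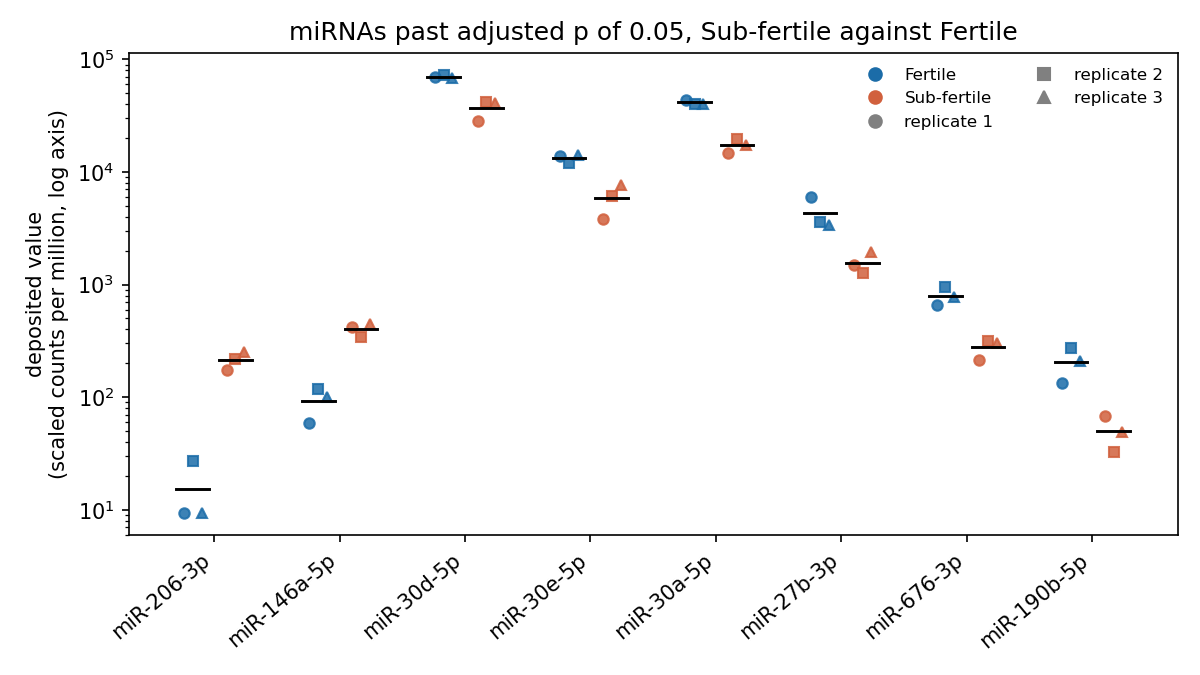
Deposited values (scaled CPM, log axis) of the 8 miRNAs past an adjusted p of 0.05 in Fertile (blue) and Sub-fertile (orange) libraries, 1 point per library and a horizontal bar for the mean (n = 3 per group). All 3 Sub-fertile libraries lie above the Fertile ones for miR-206-3p and miR-146a-5p, and below them for the other 6 miRNAs.

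The number of calls depended on single libraries. Without Sub-fertile replicate 1, 41 miRNAs passed, 13 higher and 28 lower, including all 8; without any 1 Fertile library, 3 passed, namely miR-206-3p, miR-146a-5p and miR-30a-5p. Without Sub-fertile replicate 2, 5 passed.

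Among miRNAs that did not pass, those with the smallest p in the upward direction were miR-7a-5p (log2 change 1.56, SE 0.39), miR-26b-5p (0.63, SE 0.16), miR-33a-5p (1.76, SE 0.47), miR-135a-5p (0.81, SE 0.23), miR-143-3p and miR-545-5p (2.10, SE 0.61). Their adjusted p ranged from 0.056 to 0.092. Counts were low for miR-545-5p, at 8, 7 and 2 in Fertile and 7, 7 and 32 in Sub-fertile replicates 1 to 3. For miR-33a-5p they were 18, 9 and 12 in Fertile and 21, 13 and 41 in Sub-fertile. The stromal miR-143-3p rested on 20 counts in Sub-fertile and 2 in Fertile libraries, a ratio of 17.3 with a 95% counting interval of 4.20 to 153. In the downward direction they were miR-16a-5p (-0.85, SE 0.20), miR-501-3p (-1.20, SE 0.29), miR-660-5p (-0.95, SE 0.24), miR-423-5p (-0.82, SE 0.20), miR-425-3p (-1.10, SE 0.27) and miR-378-3p (-1.96, SE 0.52), with adjusted p from 0.056 to 0.073. Of these 12, 10 passed without Sub-fertile replicate 1, which leaves 2 Sub-fertile libraries. Among them was miR-378-3p, with a log2 change of -2.66 (limma adjusted p = 1.5e-08). The library left out was the one nearest to Fertile for this miRNA. It held 2092, against 551 and 432 in Sub-fertile replicates 2 and 3 and 2769 to 3339 in Fertile. Changes are on the log2(value + 1) scale, which understates those of low miRNAs.

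Within the miR-30 family, whose members share a seed sequence, 3 of 5 measured 5p strands fell, both over all miRNAs tested and adjusted over the list alone. The other 2 did not pass: miR-30b-5p had a log2 change of -0.09 (SE 0.17) and miR-30c-5p of 0.06 (SE 0.17). The sign of miR-30b-5p flipped under plain CPM (0.03) and under thinning to equal depth (0.06). The opposite arms of the hairpins that fell did not pass either, with log2 changes of 0.03 for miR-30a-3p, 0.31 for miR-30d-3p and 0.22 for miR-30e-3p. The first of these flipped to -0.04 under quantile normalization. As a set, the family had a camera adjusted p of 0.208 with a preset correlation and of 0.819 with an estimated correlation. Members of miR-30 differ by few bases, and how their reads were assigned is not given in the sources used here.

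**Figure D4:**
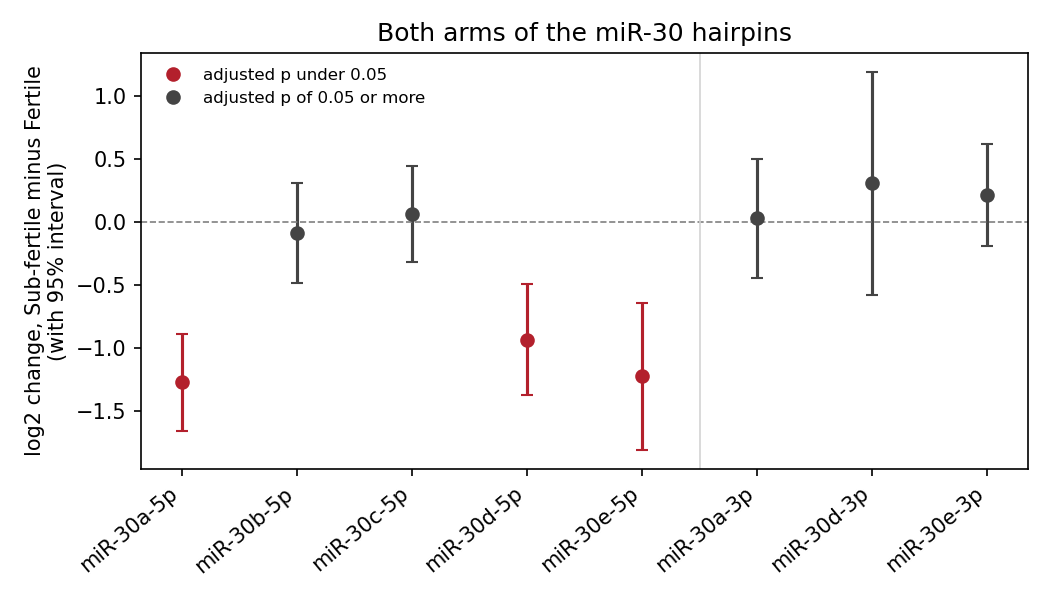
Log2 change (Sub-fertile minus Fertile, y axis) of the miR-30 5p strands and of the measured 3p strands of the same hairpins, with limma 95% intervals (n = 3 per group), red where the adjusted p was under 0.05. The intervals of miR-30a-5p, miR-30d-5p and miR-30e-5p lie below 0, and those of the other strands hold 0; miR-30b-5p and miR-30a-3p flip sign under other scalings.

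Of 23 lists of miRNA families and cell-type markers fixed before the data were examined, 19 had at least 3 members to test. None passed an adjusted p of 0.05 (limma camera), with a smallest adjusted p of 0.208. An unadjusted p under 0.05 was reached by 4 lists. They were the miR-30 family (down) and striated muscle miRNAs (up), with a camera adjusted p of 0.208 each, stromal and smooth muscle miRNAs (up, 0.225) and the miR-34 and miR-449 family (up, 0.235). With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.819, and 0 passed by fry's directional test. By fry's test of change in either direction, 4 lists passed: other epithelial miRNAs, the miR-30 family and leukocyte miRNAs (adjusted p = 0.0183 each) and the miR-15/16 family (adjusted p = 0.0444). Unlike camera, fry does not compare a list with the other miRNAs, so a few members can carry it. The miR-30 list held 3 miRNAs past the threshold and the leukocyte list 1, while the other epithelial and miR-15/16 lists held 0.

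Of 3 striated muscle miRNAs measured, 1 rose, miR-206-3p; miR-1-3p had a log2 change of 0.68 (SE 1.20), with 50.7, 1.95 and 2.32 in the Fertile libraries and 12.7 ± 5.64 in Sub-fertile (SD, n = 3). Of 8 leukocyte miRNAs, 1 rose, miR-146a-5p. Of the others, miR-223-3p had a log2 change of 1.56 (SE 1.30), miR-142-3p of 1.17 (SE 0.48), miR-155-5p of 0.45 (SE 0.41), miR-342-3p of 0.16 (SE 0.32), miR-142-5p of 0.11 (SE 0.82), miR-146b-5p of -0.28 (SE 0.22) and miR-150-5p of -0.56 (SE 0.38). Of 3 measured members of the miR-23/27/24 clusters 1 fell, miR-27b-3p. Adjusted over the list alone, 1 member passed in each of the stromal (miR-143-3p), neural and endocrine (miR-7a-5p) and miR-15/16 (miR-16a-5p) lists, none of which passed over all miRNAs. The miR-15/16 family had a median log2 change of 0.17, a mean of -0.30 and a downward camera direction.

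The miR-34 and miR-449 family, abundant in testis and in multiciliated cells, had a median log2 change of 0.91 and 0 of 6 members past the threshold. In Sub-fertile replicate 1, miR-34c-5p reached 11502 against 772 to 1842 in the other 5 libraries, and miR-449a-5p 3909 against 438 to 1050. Without this library, the log2 changes were 0.54 for miR-34c-5p, 0.67 for miR-449a-5p and 1.10 for miR-34b-5p, and miR-34b-3p passed in the downward direction (-1.63, limma adjusted p = 0.00026). Without Sub-fertile replicate 3, this list passed (camera adjusted p = 0.0268), but not with an estimated correlation (camera adjusted p = 0.616). Of the 7 measured other epithelial miRNAs 0 passed; miR-182-5p had a log2 change of -0.52 (SE 0.17), miR-375-3p of -0.77 (SE 0.30) and miR-96-5p of 0.47 (SE 0.24).

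No member of the remaining lists passed over all miRNAs tested. The list of the miR-10 family and HOX-linked miRNAs, which holds miR-196a-5p and miR-196b-5p as well, had a median log2 change of -0.15. Other median log2 changes were 0.10 for the let-7 family, 0.14 for the miR-17~92 cluster and paralogs and 0.06 for the miR-29 family. They were 0.02 for the miR-181 family and 0.23 for the miR-148 and miR-152 family. They were -0.21 for the germ cell and testis X-linked list, 0.03 for the neural and endocrine list and 0.13 for the imprinted DLK1-DIO3 cluster. The hypoxia and oxidative stress list had 0.40 and passenger strands -0.22. Without Sub-fertile replicate 1, the X-linked members changed by 0.26 (miR-508-3p), 0.19 (miR-507-3p) and -0.40 (miR-506-3p), so the sign of that median rested on this library. The other 4 lists had too few measured members to test: the miR-200 family (2), pluripotency and early germ cell (1), erythroid and platelet (1) and liver miRNAs (0).

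Vesicles held 228.7 ± 2.1 miRNAs at 10 or more in Fertile and 230.7 ± 8.6 in Sub-fertile (SD, n = 3 each; two-sided exact permutation p = 0.8). The most abundant miRNA took 13.2% ± 1.33 and 12.5% ± 0.970 of the total (exact permutation p = 0.5), and the top 10 of each library 58.4% ± 0.528 and 59.1% ± 3.33 (exact permutation p = 0.9). Shannon entropy was 5.12 ± 0.0446 and 5.13 ± 0.136 bits (exact permutation p = 1). With 3 libraries against 3, or 2 against 3, the smallest p this test can give is 0.1, so it cannot reach 0.05. Without Sub-fertile replicate 1, the difference in top 10 share (Sub-fertile minus Fertile) went from 0.655 to 2.57 percentage points (exact permutation p = 0.1). That in entropy went from 0.0104 to -0.0680 bits (exact permutation p = 0.2). That in miRNAs at 10 or more went from 2 to -2.67 (exact permutation p = 0.5).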

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

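Plain CPM and thinning to equal depth were chosen after the data were examined; the other settings were planned. The 8 miRNAs kept their direction in every setting that tested them. Other pseudocounts, no filter, filters at 1 or on a mean of 10, robust limma and edgeR on recovered counts called 8 each, the same 8 as the main test. The count was 9 with median-of-ratios scaling, 7 with plain CPM, 6 without the 5 most abundant miRNAs and 6 after thinning (2 to 9 over 20 draws). A filter at 100 gave 14, quantile normalization 5 (3 higher and 2 lower), limma without a trend 1 (miR-206-3p), array weights 45 (15 higher and 30 lower) and DESeq2 17 (10 higher and 7 lower). At a filter of 100 fewer miRNAs were tested (131), and array weights gave Sub-fertile replicate 1 a weight of 0.188; for the other settings the cause was not tested. The median log2 change of all tested miRNAs was -0.10, against 0.02 with plain CPM, 0.04 after thinning and 0.06 with DESeq2.

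Leaving out 1 library gave 3 to 41 miRNAs: 3 without Fertile replicate 1, 2 or 3, 41 without Sub-fertile replicate 1, 5 without replicate 2 and 9 without replicate 3 of that group. Calls on lists ranged from 0 to 1, the 1 being the miR-34 and miR-449 family without Sub-fertile replicate 3, and were 0 in the other settings run for lists (pseudocounts 0.5 and 5, filters at 1 and 100, median-of-ratios, quantile, plain CPM, replicate block, estimated correlation and the other libraries left out). With the replicate number as a block, 0 miRNAs passed (limma, 43 at an unadjusted p under 0.05). Same-numbered libraries deviated with correlations of 0.045, -0.116 and 0.105, and in no pair were both libraries the best match of each other. These values show no pairing by number, but 3 pairs are too few to exclude it. Counted at 1 or more, detected miRNAs differed by -18.3 (exact permutation p = 0.3), where depth sets the floor. Depth limits low miRNAs most: 1 count was worth 6.24 units in Sub-fertile replicate 1.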

Other observations

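Apart from the counts over other splits of the samples, the tests in this part were chosen after the data were examined. For the thinning tests of miR-30, of the genomic cluster and, as a single draw, of Sub-fertile replicate 1, the deciding value was fixed before thinning was run; the other tests, 20-draw thinning included, were chosen after the result was seen. Beyond the comparisons above, 8 miRNAs of 1 genomic neighbourhood (miR-660-5p, miR-532-5p, miR-501-3p, miR-502a-3p, miR-500-3p, miR-532-3p, miR-502b-3p and miR-188-5p) were all lower in Sub-fertile vesicles, with log2 changes from -2.03 to -0.50 and a median of -1.05. None passed alone. The ratio of the 5p to the 3p strand changed in 4 of 57 hairpins (limma adjusted p = 0.0489 each): it fell for miR-30a (-1.30) and miR-30e (-1.44) and rose for miR-34b (2.92) and miR-196a (1.42). With any 1 library left out, 0 hairpins passed, with changes of the same sign.

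A hypothesis for the cluster is that neighbouring miRNA genes change together. Among 29 clusters it alone passed with camera (adjusted p = 0.00649), and it passed with each library left out (0.00215 to 0.0463), but with an estimated correlation the adjusted p was 0.520. Lower depth of the Sub-fertile libraries may add to it. After 1 thinning draw the median change was -0.769, against -1.05 before (unadjusted camera p = 0.0031, preset correlation). In that draw depth did not account for the whole. Other draws were not run for the cluster, so the part of depth is not settled. The 8 members are not 8 independent measurements, since miR-532-5p and miR-532-3p are arms of 1 hairpin. How reads were assigned among the members is not given in the sources used here, and reads shared between them were not tested for. The preset correlation of 0.01 allows little for such dependence. The pattern was found and tested on the same data.

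The lower 5p strands of miR-30a, miR-30d and miR-30e could come from lower output of their hairpins. Against this, the mean 5p-minus-3p change over the 3 hairpins was -1.33 (95% interval -2.07 to -0.59, exact permutation p = 0.1). The ratio of miR-30d alone did not pass (limma adjusted p = 0.167). The hairpins were chosen for lower 5p strands in these same libraries, which favours negative values here and in the tests that follow. Their 3p strands, not chosen in this way, had log2 changes of 0.03 (miR-30a), 0.31 (miR-30d) and 0.22 (miR-30e). Reads moved between near-identical members are argued against by the sum of the 5 strands, which changed by -1.02 (-1.47 to -0.57). After thinning, the mean change of the 3 lower strands was -1.05 (-1.42 to -0.68), against -1.15 before. These strands had 615 counts or more in every library, so thinning could hardly change them. It speaks to counting error alone, and other differences that go with low depth were not tested. Selective loading or stability of 1 arm, a difference in the cells that shed vesicles and ligation bias stay open and were not tested. A role of semen quality is likewise a hypothesis.

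The higher miR-206-3p could stem from striated muscle RNA, but the counts allow at most 18.7 units of summed miR-133a-3p and miR-133b-3p in any Sub-fertile library (3 counts per library), where miR-206-3p lay 148 to 225 above the highest Fertile library. Whether reads of these 2 strands were lost in read assignment was not tested; miR-1-3p, also abundant in muscle, stood at 12.7 ± 5.64 in Sub-fertile and at 50.7, 1.95 and 2.32 in the Fertile libraries. Leukocyte RNA could raise miR-146a-5p: the 7 other leukocyte miRNAs had a median log2 change of 0.160 (SD 0.76, 5 of 7 higher), and such a source cannot be told apart from a change of miR-146a-5p alone because they moved both ways. They ranged from -0.56 for miR-150-5p to 1.56 (SE 1.30) for miR-223-3p.

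Sub-fertile replicate 1 had a median r with the other libraries of 0.920, where the lowest other was 0.949; this could be its low depth. In the single draw at equal depth it was 0.899 against a lowest other of 0.898, as low depth would give, but over 20 draws it lay below every other library in 15, and over the 132 miRNAs with a mean of 100 or more in 13. At equal depth a median of 10 of those 132 (8 to 11 over draws) lay over 2-fold outside the range of the other libraries, where the other medians were 0 to 5 and single draws reached 8. By draws, this comparison leaves depth open. At full depth 13 lay outside. When each other library alone was thinned to this depth, at most 9 of its miRNAs did (medians 0 to 6). The mean of 100 counted Sub-fertile replicate 1 itself. Among the 13, miR-371-3p, miR-34c-3p and miR-15b-5p reached that mean only with this library included. The choice of miRNAs thus raised its number, and this comparison also leaves depth as the whole cause open. For the correlations, depth cannot be told apart from a real difference of this sample, since the draws went both ways. A larger share of testis RNA that carries both testis lists alike is argued against by their changes in this library. The X-linked testis list (3 of 22 named members measured) had a median log2 change of -1.07 (SD 0.35). The miR-34 and miR-449 list had one of 2.47 (SD 1.39). Testis RNA rich in the miR-34 and miR-449 family alone was not tested and stays open. Its miR-371-3p reached 755.6 against 26.1 to 109.0 elsewhere.

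The 6 libraries allow 10 splits into 3 and 3, too few to give a share under 0.05. For differing miRNAs, 1 split, the real one, gave 8 or more, and the highest other gave 0; for arm ratios, 1 split gave 4 or more, and the highest other 0. For lists, all 10 splits gave at least the real 0, with a highest other of 3. For clusters, 4 splits gave at least the real 1, and the split of Fertile replicates 1 and 3 with Sub-fertile replicate 3 against the rest gave 5. These counts use the preset correlation, and with an estimated one 0 clusters passed in any split. Whether the 5 reflect a structure of the samples other than the groups or chance calls was not tested.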
